A study of Rattus norvegicus with 5 samples.

How the data were processed

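The series holds 5 samples of total RNA from rat hippocampus, labelled P5, each measured on 1 single-colour oligonucleotide array with 8799 probe sets. Per the labels, 2 samples belong to a control diet, 2 to fetal alcohol exposure and 1 to an isocaloric diet. The labels do not say whether samples of a group came from separate animals or pools, so the spread between these samples may in part be technical. The p-values of single probe sets rest on this spread, in part borrowed across probe sets.

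The deposited values are intensities, 1 per probe set and array, on a linear scale without negative values. The software and the scaling steps that produced them are not given in the sources used here. The 2% trimmed mean of the deposited intensities lay between 150.19 and 150.22 on the 5 arrays, a ratio of 1.0002 between the highest and the lowest. By a rule fixed before the data were examined, columns whose trimmed means lay within a factor of 1.1 were taken as already scaled and used as deposited. Detection calls and scan dates were not used here, so no scan batch was tested. The number of arrays limits the precision. The labels give no meaning to the replicate numbers beyond a name, and with 2 arrays per group the deviations of same-numbered arrays from their group means give 1 correlation, -0.113, which cannot show whether the numbers pair the samples; they were not used as pairs. No pair of arrays held identical columns, and every value column was matched to a sample.

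The 59 control probe sets were left out of the tests and used only to describe the arrays. Intensities of the other 8740 probe sets became log2(intensity + 10.605), where the offset is the 20th percentile of all their values, so a log2 difference understates the change of a dim probe set. Probe sets whose mean log2 value over the 5 arrays was under the 40th percentile were not tested, which left 5244. Gene names came from the platform annotation, with the current symbol looked up through the gene identifier for 6985 probe sets, whether or not it differed. Of the 8740, 7006 had exactly 1 gene symbol, 308 had several and 1426 had none; genes were named only from the first kind.

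The 3 comparisons, fetal alcohol against control diet, fetal alcohol against isocaloric diet and isocaloric against control diet, were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, an intensity trend in the variance and 2-sided tests. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. The fit had 2 residual and 6.30 prior degrees of freedom. The spread came from the control diet and the fetal alcohol arrays, and the single isocaloric array, which has no replicate check, was assumed to vary like them. As a description without a test, probe sets were also counted whose fetal alcohol arrays both lay above or both below the control diet arrays with a mean difference of at least 1.5-fold; chance puts 33.3% of probe sets without overlap in this way.

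A total of 33 gene lists, fixed before the data were examined, covered cell types, neighbouring tissues, signalling, metabolism and protein complexes. They were tested with camera in limma at a preset correlation of 0.01 between genes, with 1 probe set per gene (the brightest on average), over 3174 genes, for lists with at least 5 tested genes. Camera compares the genes of a list with all other genes. At this preset its p-values rest on the spread across genes, taken as nearly independent, rather than on that between samples. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. Each list's median was placed among 10000 random lists of the same size matched on mean intensity. Because the 2 differences from control diet share their control arrays, their correlation was set beside 100 simulations of unchanged groups. These gave every group the same spread.

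The genes named follow a rule fixed before the data were examined. It takes probe sets past the threshold, largest difference first, up to 12 higher and 12 lower for fetal alcohol against control diet and up to 6 and 6 for the other comparisons. Where too few pass, the places go to the smallest p-values among those at least 1.5-fold apart, without overlap in the first comparison. It also takes 18 genes of prior interest whatever their values, and the 2 to 4 members of a described list with the largest differences. Of the 18 genes, 1 is not reported here, Gfap and Hba1 had no probe set with exactly 1 symbol and Nr3c1 was under the intensity filter. Where a gene had several probe sets, the one with the smallest p was ranked, and the brightest stood for the gene in lists and among the genes of prior interest.

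The fit was tested on simulated arrays with the real means and moderated spread over 5244 probe sets, 200 of them changed, in 10 simulations per comparison. For fetal alcohol against control diet, 67.4% of probe sets changed by 1 on the log2 scale and 100% of those changed by 2 were recovered. False calls averaged 13.5 per simulation there. For fetal alcohol against isocaloric diet these shares were 35.4% and 99.2%, and for isocaloric against control diet 36.4% and 98.6%. With the moderated spread and 200 changed probe sets, these shares may overstate the recovery in the real data. There, Ttr (-4.16), Igf2 (-2.50) and Sod3 (-2.06) did not pass for fetal alcohol against control diet. In 10 simulations of fetal alcohol against control diet over 3174 genes with 1 list shifted by -0.5, the preset correlation found the list 10 times, the estimated correlation 0 times and fry 0 times. The simulated genes varied independently, which favours the preset correlation.

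The alternatives were quantile normalization, scaling to equal medians, 2 other offsets, 2 other filters, a fit without the intensity trend, each control diet and fetal alcohol array left out in turn, other sets of arrays in the fit, a replicate block, other list tests and stricter rules of size. No genome was used here, so no sequence property was tested.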

Results

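Transcript levels were measured in hippocampus samples from rats labelled P5, on 5 arrays: 2 from control diet, 2 from fetal alcohol exposure and 1 from an isocaloric diet, a feeding control for alcohol diets. The median intensity was 53.3 and 54.7 on the control diet arrays, 49.0 and 55.7 on the fetal alcohol arrays and 51.6 on the isocaloric array. The control diet arrays were the closest of the 10 pairs, with an SD of log2 differences of 0.341, and the fetal alcohol arrays the farthest apart, with 0.509. The ratio of the 3' to the 5' probe set of beta-actin was 1.32 and 1.34 on the control diet arrays, 1.18 and 1.26 on the fetal alcohol arrays and 1.12 on the isocaloric array. Spiked control RNA gave more signal on the control diet arrays: Cre measured 3332 and 3792 there, 1795 and 2511 on the fetal alcohol arrays and 1693 on the isocaloric array.

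The comparison of fetal alcohol with control diet asked which transcripts of the developing hippocampus differ after alcohol exposure before birth. Genes of the choroid plexus, the epithelium that makes cerebrospinal fluid next to the hippocampus, fell as a group. The median log2 difference of the 8 genes tested was -0.87, with 7 of 8 negative, and camera gave an adjusted p of 1.3e-06. With an estimated correlation between genes this list did not pass (adjusted p = 0.555), nor with fry (0.353). Ttr, which encodes transthyretin, the carrier of thyroid hormone and of retinol-binding protein, measured 5297 and 4886 on the control diet arrays and 1004 and 69.2 on the fetal alcohol arrays. The isocaloric array had a Ttr intensity of 5391. The Ttr log2 difference from control diet was -4.16 ± 0.92 (SE), and its adjusted p over all probe sets was 0.488. Without fetal alcohol array 1 it was -5.998 (adjusted p = 7.66e-07) and without array 2 -2.33 (0.00274), in fits whose spread came from the control diet arrays; over all alternatives the adjusted p reached 0.9996. A second Ttr probe set measured 6228 and 5728 on the control diet arrays, 1276 and 19.3 on the fetal alcohol arrays and 5745 on the isocaloric array. Aqp1, a water channel, had a log2 difference of -1.21 ± 0.24, Sostdc1, a secreted antagonist of bone morphogenetic proteins, one of -1.14 ± 0.27, and Enpp2, the enzyme autotaxin, one of -1.0 ± 0.25. These 4 genes passed when p-values were adjusted over the list alone, and none of them when adjusted over all probe sets. The 1 member with a positive difference, named after its value was seen, was Prlr, the prolactin receptor, with 0.04 ± 0.24.

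**Figure D1:**
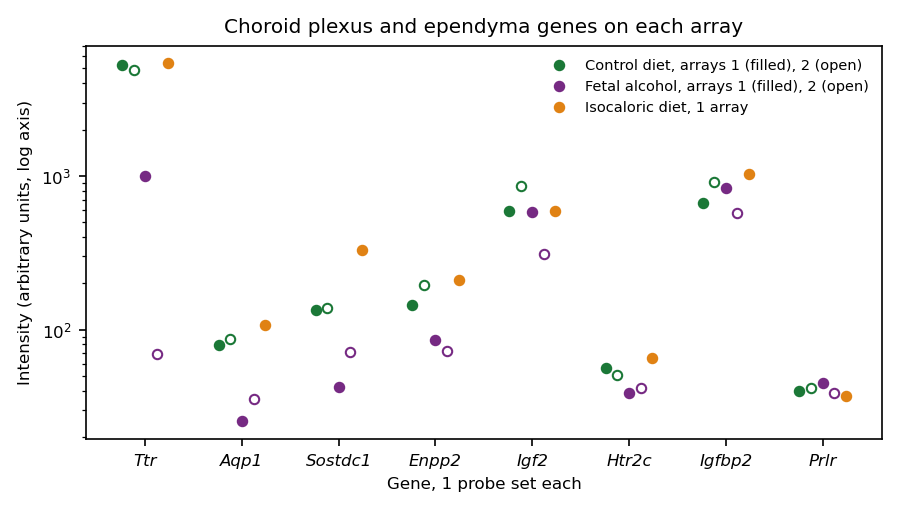
Intensity (log axis, arbitrary units) of the 8 tested choroid plexus and ependyma genes, 1 probe set each, on the 2 control diet, 2 fetal alcohol and 1 isocaloric array; each point is 1 array. Ttr stands at 5297, 4886 and 5391 on the arrays without alcohol and at 1004 and 69.2 on the fetal alcohol arrays.

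Genes of the meninges and connective tissue also fell as a group, with a median log2 difference of -0.40 and negative values in 19 of 21 genes (camera adjusted p = 5.85e-06). With an estimated correlation this list and the next 2 did not pass, each at an adjusted p of 0.555. The estimated correlation was 0.428 for the meninges genes, the highest of the 33 lists, so they are not independent of one another. The largest differences in this list were those of Col3a1, a fibrillar collagen (-1.14 ± 0.54), Aldh1a2, a retinoic acid synthesising enzyme (-0.86 ± 0.33), Igf2 (-0.74 ± 0.34) and Col1a1 (-0.68 ± 0.35). On fetal alcohol array 1, Col3a1 (304) and Col1a1 (944) lay within the range of the control diet arrays (290 and 408, 886 and 1307). Igf2 and Igfbp2 stand in both this list and the choroid plexus list. Neural progenitor and neurogenesis genes fell with a median of -0.25, with 13 of 20 negative (camera adjusted p = 0.0166). Among them Id3, an inhibitor of basic helix-loop-helix factors, had -0.77 ± 0.24, Nnat, neuronatin, -0.68 ± 0.19, and Dll1, a Notch ligand, -0.65 ± 0.26. Genes of alcohol, aldehyde and retinoid metabolism fell with a median of -0.13, with 16 of 21 negative (camera adjusted p = 0.0166). The median ranged from -0.26 to -0.15 with 1 array left out and reached -0.087 under another alternative. This list holds Ttr and Aldh1a2, and next came Rara, a retinoic acid receptor, with -0.84 ± 0.32. No member of the meninges and progenitor lists passed when adjusted over the list alone, and in the retinoid list 1 did, Ttr. Without choroid plexus and meninges genes, an alternative chosen after seeing the data, the retinoid list had a median of -0.12, close to that of the full list, and an adjusted p of 0.162. Single arrays decided part of these calls. Without fetal alcohol array 2 the meninges list had a median of -0.18 (adjusted p = 0.396) and the retinoid list one of -0.17 (0.397). Without fetal alcohol array 1 the progenitor list had a median of -0.14 (0.282). Without control diet array 2 it had one of -0.16 (0.117), and the retinoid list one of -0.15 (0.069). With the filter at the 60th percentile the retinoid list also had a median of -0.12 (0.0717). Over all alternatives it ran from 3.86e-11 to 0.555 for the choroid plexus list, from 1.79e-11 to 0.614 for the meninges list, from 0.0038 to 0.614 for the progenitor list and from 0.00012 to 0.614 for the retinoid list.

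Among single probe sets, the smallest p-values belonged to lower signals after fetal alcohol, and none passed the threshold. For Igf2, insulin-like growth factor 2, probe set E00988mRNA_s_at measured 134 and 179 on the control diet arrays, 23.1 and 14.7 on the fetal alcohol arrays and 27.0 on the isocaloric array, a log2 difference of -2.50 ± 0.27 (limma adjusted p = 0.0547). The 3 other Igf2 probe sets had smaller differences of -0.74, -0.52 and -0.11. Sod3, extracellular superoxide dismutase, measured 119 and 103 against 25.5 and 13.0 (log2 difference -2.06 ± 0.27, adjusted p = 0.132), and 104 on the isocaloric array. Gsta1, a glutathione transferase with both fetal alcohol values under the offset, differed by -1.94 ± 0.29, Sec31a, a coat protein of vesicles leaving the endoplasmic reticulum, by -1.93 ± 0.27, and Atn1, the corepressor atrophin 1, by -1.75 ± 0.27, each with an adjusted p of 0.132. The other 2 Gsta1 probe sets gave -1.30 and -0.77. The other 2 Sec31a probe sets gave -0.09 and -0.44, and other probe sets of Atn1, Mras and Mrpl38 also had smaller differences, of -0.71, -0.29 and -0.32. Those of Ptms gave -0.76 and -0.79. Enpp2 (-1.51 ± 0.25, at its second probe set), the GTPase Mras (-1.41 ± 0.24), the leukotriene synthesis protein Alox5ap (-1.40 ± 0.24), the chemokine receptor Cxcr1 (-1.40 ± 0.26), Mrpl38 of the mitochondrial ribosome (-1.38 ± 0.28), Ptms (-1.21 ± 0.25) and Aqp1 completed the 12, with adjusted p-values from 0.178 to 0.383. At the ranked probe sets, isocaloric minus control diet gave -2.14 for Igf2, -2.07 for Sec31a, -1.71 for Atn1 and -1.35 for Ptms. Mrpl38 had -1.26, Cxcr1 -1.001 and Mras -0.896 in that difference. For these genes the isocaloric array thus also lay below both control diet arrays. Sod3 had -0.09, Alox5ap 0.11, Aqp1 0.33, Enpp2 0.78 and Gsta1 1.24.

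The 12 ranked genes with higher signal after fetal alcohol had log2 differences between 0.75 and 1.76 and adjusted p-values from 0.529 to 0.682, so none passed. Dnaaf9, a dynein assembly factor, had 1.76 ± 0.45, with a range of 0.97 to 2.54 when 1 array was left out and a value under the offset on control diet array 1, Stk38, a kinase, 1.36 ± 0.34, Pex19, a peroxisome import factor, 1.04 ± 0.26, and Kctd13, an adaptor of a ubiquitin ligase, 1.02 ± 0.24. Thy1, a surface glycoprotein of neurons, measured 752 and 755 on the control diet arrays, 1622 and 1185 on the fetal alcohol arrays and 786 on the isocaloric array, a log2 difference of 0.87 ± 0.23. Other probe sets of these genes had smaller or no differences: -0.23 and -0.02 for Kctd13, 0.27 for Stk38 and 0.28 for Thy1. The others were Plpp2, Atp5if1, Lin7b, Pfkp, Prickle2, Copb2 and Ralb. A second probe set gave -0.05 for Plpp2, 0.15 for Copb2, 0.76 for Pfkp, 0.59 for Prickle2 and 0.34 for Ralb. The other Atp5if1 probe sets gave 0.70, 0.64 and 0.24. Isocaloric minus control diet gave 1.84 for Plpp2, 1.74 for Dnaaf9, 1.63 for Stk38, 1.41 for Atp5if1, 0.85 for Copb2, 0.65 for Ralb and 0.64 for Prickle2. It gave 0.62 for Pfkp, 0.60 for Kctd13, 0.22 for Pex19, 0.06 for Thy1 and -0.25 for Lin7b.

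Of the 14 tested genes of prior interest, Ttr and Igf2 (-0.74 ± 0.34 at its brightest probe set, -1.18 to -0.29 when 1 array was left out) had the largest differences, given above. The other 12 had smaller ones. Gap43, a protein of growth cones, measured 3029 and 2563 on the control diet arrays and 2568 and 3070 on the fetal alcohol arrays, a log2 difference of 0.01 ± 0.19. Elavl4, a neuronal RNA-binding protein, had 0.08 ± 0.23, Ntrk2 0.17 ± 0.28, Igf1 0.08 ± 0.24, Npy 0.01 ± 0.24 and Gad1, which makes GABA, -0.04 ± 0.28. Bdnf had -0.28 ± 0.23, Fos -0.28 ± 0.26, Mbp 0.24 ± 0.30, Grin2b 0.34 ± 0.23, Grin1 0.09 ± 0.31 and Gria2 -0.05 ± 0.24. A second probe set gave 0.15 for Bdnf and -0.71 for Fos. None of these 12 passed, which does not show that they did not differ. The list of axon growth genes had a median of -0.06, with 25 of 35 negative (camera adjusted p = 0.128), and hippocampal excitatory neuron genes one of -0.02 over 9 genes (adjusted p = 0.98).

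Over all 5244 probe sets, limma found 0 past the threshold, and 294 at an unadjusted p under 0.05 (87 higher and 207 lower). If no probe set differed, 262.2 would be expected. By the rule of size, 286 probe sets differed (81 higher and 205 lower), and 34.5% of probe sets did not overlap, against 33.3% by chance. Setting control diet array 1 and fetal alcohol array 2 against the other pair also gave an uneven count, 95 in one direction and 198 in the other, and the third split of these 4 arrays gave 192 and 16. With the isocaloric array also required on the control side, 148 were left (40 higher and 108 lower). Quantile normalization put 1 probe set past the threshold (Igf2) and scaling to equal medians 5 (Igf2, Sod3, Sec31a, Gsta1 and Atn1). Without fetal alcohol array 1 the count was 17 and without array 2 it was 25, in fits whose spread came from the control diet arrays.

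The comparison of fetal alcohol with isocaloric diet asked how fetal alcohol exposure compares with a feeding control, here 1 array. Choroid plexus genes fell here too, with a median of -0.95, 7 of 8 negative and a camera adjusted p of 1.45e-08. With an estimated correlation none of the 3 lists called in this comparison passed: the adjusted p was 0.639 for the choroid plexus and ribosomal lists and 0.668 for the kinase C list. Ttr had a log2 difference of -4.25 ± 1.13 (-6.08 and -2.41 without fetal alcohol array 1 and 2), Sostdc1 -2.37 ± 0.33, Aqp1 -1.54 ± 0.29 and Enpp2 -1.31 ± 0.30, and these 4 passed when adjusted over the list alone. Ribosomal protein genes fell by less, with a median of -0.25 and negative values in 35 of 37 genes (adjusted p = 3.05e-07). Against control diet the same list had a median of -0.06, with 21 of 37 negative, and did not pass (adjusted p = 0.214). Rpl35a had -0.82 ± 0.29, Rpl41 -0.69 ± 0.28 and Rps3a -0.64 ± 0.41. Genes of kinase C, calcium and calmodulin signalling rose, with a median of 0.27 and positive values in 25 of 30 (adjusted p = 0.00435). Against control diet their median was 0.096, which did not pass (adjusted p = 0.121). Itpka, which phosphorylates inositol trisphosphate, had 1.14 ± 0.35, Plcb3, a phospholipase C, 1.09 ± 0.28, and Camkk2, a calmodulin-dependent kinase kinase, 0.79 ± 0.29. No member of the ribosomal and kinase C lists passed when adjusted over the list alone. Meninges genes had a median of -0.26 and did not pass (adjusted p = 0.093).

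Without fetal alcohol array 2 the kinase C list had a median of 0.14 and an adjusted p of 0.157, within a range of 0.00027 to 0.668 over all alternatives. The choroid plexus list ranged from 2.62e-12 to 0.639, with medians from -1.31 with the filter at the 60th percentile to -0.52 with no filter, and the ribosomal list from 1.9e-07 to 0.639.

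No single probe set passed in this comparison (smallest limma adjusted p = 0.0714), and 221 had an unadjusted p under 0.05 (140 higher and 81 lower). If no probe set differed, 262.2 would be expected. Gsta1 had the smallest p: it measured 8.50 and 4.77 on the fetal alcohol arrays and 144 on the isocaloric array, a log2 difference of -3.17 ± 0.35; both fetal alcohol values lay under the offset, and its other 2 probe sets gave -1.90 and -1.16. The next were Enpp2 with -2.28 ± 0.30, Sostdc1, Sod3 with -1.97 ± 0.34, Aqp1 and Alox5ap with -1.52 ± 0.29. The 6 ranked genes with higher signal each had an adjusted p of 0.986. Grin2d, an NMDA receptor subunit, had 1.19 ± 0.28 and Gabbr1, a GABA-B receptor subunit, 1.20 ± 0.29. Both measured less on the fetal alcohol than on the control diet arrays (log2 differences -0.61 and -0.61), and least on the isocaloric array. For Grin1, probe set S39221_at had 1.16 ± 0.28 and the brightest, S39221_g_at, -0.08 ± 0.39, while the 2 others had 0.28 and 0.91. Sstr2, a somatostatin receptor, had 1.17 ± 0.29, Tubb5 1.13 ± 0.28 and Dock8 1.61 ± 0.40, with an isocaloric value under the offset for Dock8. Other probe sets gave -0.02 for Grin2d, -0.02 for Tubb5, at the brighter probe set, and -0.04 and -0.02 for Dock8. Gap43 had 0.06 ± 0.23, Elavl4 0.37 ± 0.28 and Fos 0.82 ± 0.32, none of which passed; the second Fos probe set gave -0.41. The counts past the threshold became 3 under quantile normalization and 3 under equal medians, 10 without fetal alcohol array 1 and 12 without array 2.

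The comparison of isocaloric with control diet concerns the feeding control itself and rests on 1 array against 2. Ribosomal protein genes rose, with a median of 0.26 and positive values in 29 of 37 (camera adjusted p = 0.00421). With an estimated correlation none of the 5 lists called between the diets passed, each at an adjusted p of 0.77. Rpl35a had 0.84 ± 0.29, Rps3a 0.69 ± 0.41 and Rpl36 0.62 ± 0.28. Proteasome and ubiquitin genes rose with a median of 0.32, with 17 of 25 positive (adjusted p = 0.0444). Psma6 had 0.89 ± 0.33 and Psmc5 0.73 ± 0.28, while Psme1, of the proteasome activator, had -0.78 ± 0.27. Synaptic vesicle and release genes fell, with a median of -0.30 and negative values in 22 of 32 (adjusted p = 0.00895). Rab3a, a GTPase of synaptic vesicles, measured 820 and 804 on the control diet arrays, 296 on the isocaloric array and 481 and 543 on the fetal alcohol arrays, and Cplx1, complexin 1, had a log2 difference from control diet of -1.42 ± 0.29. Glutamate receptor genes fell with a median of -0.30, with 17 of 25 negative (adjusted p = 0.0364), and growth factor and neurotrophin genes with a median of -0.16, with 20 of 33 negative (adjusted p = 0.0444). Grin2d had -1.80 ± 0.28 and Shank1, a postsynaptic scaffold, -0.96 ± 0.39. Among growth factor genes, Fgfr1 had -1.11 ± 0.32 and Irs2, an insulin receptor substrate, -0.96 ± 0.35. Rab3a and Cplx1 passed when adjusted over the synaptic list alone and 1 gene over the glutamate list. None did in the other 3 lists. Choroid plexus genes had a median of 0.28 and did not pass (adjusted p = 0.159). Among them Sostdc1 had a log2 difference of 1.22, Aqp1 0.33, Enpp2 0.31, Ttr 0.08 and Igf2 -0.26.

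Without control diet array 2 the adjusted p was 0.113 for the glutamate list, 0.134 for the proteasome list and 0.238 for the growth factor list, whose median moved to -0.06. Over all alternatives these 3 ranged from 0.006, 0.006 and 0.0156 up to 0.77. Quantile normalization ended the same 3 calls, with medians of -0.28, 0.29 and -0.13 and adjusted p-values of 0.0523, 0.139 and 0.0689. Scaling to equal medians ended that of the proteasome list, with a median of 0.36 (0.0515). With the filter at the 60th percentile all 3 ended: the medians of the glutamate and growth factor lists moved to -0.0997 (0.289) and -0.056 (0.264), and that of the proteasome list stayed at 0.32 (0.128). With no filter the glutamate list had -0.19 (0.0578) and the growth factor list -0.10 (0.461). Leaving out 1 array at a time gave medians of the growth factor list from -0.34 to -0.06.

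**Figure D2:**
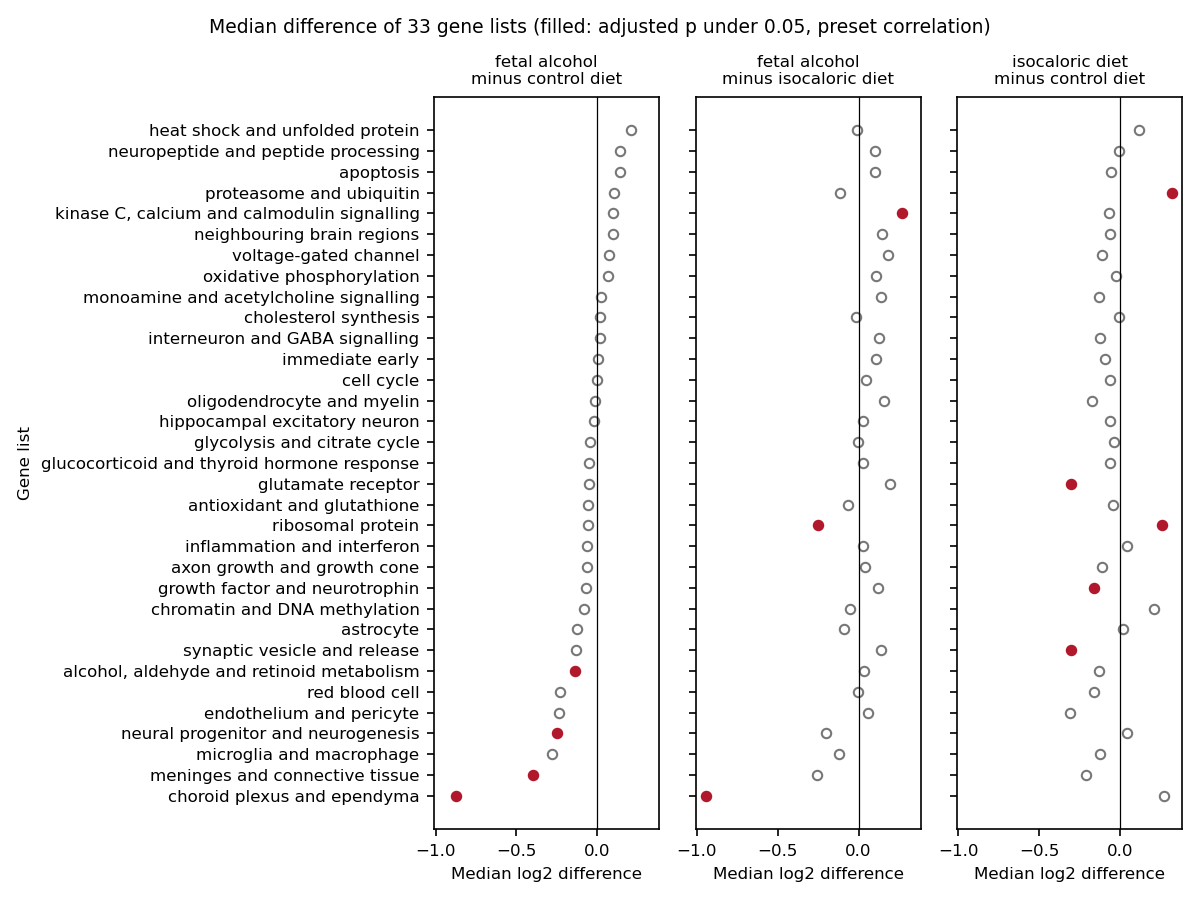
Median log2 difference (horizontal axis) of the 33 gene lists (vertical axis) in the 3 comparisons; each point is 1 list, filled where its camera adjusted p was under 0.05 at the preset correlation. Choroid plexus and ependyma genes lie at -0.87 and -0.95 in the comparisons with fetal alcohol and at 0.28 in that of the diets.

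No probe set passed between the diets (smallest limma adjusted p = 0.27), and 357 had an unadjusted p under 0.05 (72 higher and 285 lower). If no probe set differed, 262.2 would be expected. The ranked genes with lower signal were Igf2 (-2.14 ± 0.33, probe set E00988mRNA_s_at), Sec31a (-2.07 ± 0.33), Epn1, an endocytic adaptor (-1.83 ± 0.34), Gabbr1 (-1.81 ± 0.29), Grin2d, and Scarb1, a lipoprotein receptor (-1.80 ± 0.33). Those with higher signal were Plpp2 (1.84 ± 0.35), Stk38 (1.63 ± 0.41), Ankrd24 (1.49 ± 0.34), Atp5if1 (1.41 ± 0.32), Clpb (1.14 ± 0.27) and Atp5po, a subunit of ATP synthase (1.04 ± 0.28). Other probe sets gave smaller differences or the opposite sign for several of these genes: -0.12 for Plpp2, 0.44 for Stk38, 0.13 for Clpb, 0.10 and -0.53 for Scarb1, -0.21 for Grin2d, -0.66 and -0.86 for Sec31a, and 0.07, -0.11 and -0.26 for Igf2. Gabbr1 had -1.58, -1.14 and -0.09 at its others. Fos had -1.10 ± 0.32, with -0.29 at its second probe set, and Gap43 -0.05 ± 0.23. The count past the threshold was 11 without fetal alcohol array 1 and 13 without array 2.

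Igf2, Sec31a, Stk38, Plpp2 and Atp5if1 stood among the ranked genes of both comparisons with control diet. Across the 5244 probe sets the differences of fetal alcohol and of isocaloric diet from control diet had a Pearson correlation of 0.5. Probe sets are not independent replicates, and shared control arrays alone gave 0.41 on average in 100 simulations (0.376 to 0.462). The covariance was 0.0655, against 0.048 simulated (highest 0.0553). The simulations gave every group the same spread. The control diet arrays were closer to each other (SD of log2 differences 0.341) than the fetal alcohol arrays (0.509). The simulated covariance thus overstates the part due to the shared control arrays. With a different control array for each difference, the correlation was 0.259 or 0.197.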

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

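The tests of lists without choroid plexus and meninges genes and of crossed replicate numbers were chosen after the data had been seen. The choroid plexus list kept its sign and stayed past the threshold under 16 of 18 alternatives against control diet and 13 of 15 against isocaloric diet. These include the lists without choroid plexus and meninges genes, where genes left only the other lists, so this pass was fixed in advance. The exceptions were the estimated correlation and fry, under which 0 lists passed in each of the 3 comparisons; in simulated data both methods also missed nearly all shifted lists. None of the 12 lists past the test reversed under any alternative run. Other counts of lists past the test changed as follows. Between the diets, 2 lists passed under quantile normalization, 3 with no filter, 2 with a filter at the 60th percentile and 10 with all probe sets of a gene; for fetal alcohol against isocaloric diet 5 passed with all probe sets. Leaving out 1 array at a time gave 2 to 8 lists for fetal alcohol against control diet (8 without control diet array 1, 2 without control diet array 2 or fetal alcohol array 2). It gave 2 to 9 against isocaloric diet (9 without fetal alcohol array 1, 2 without fetal alcohol array 2) and 2 to 8 between the diets (8 without control diet array 1, 2 without control diet array 2).

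Counts of probe sets past the threshold rose from 0 to 1 under quantile normalization, 5 under equal medians and 1 with the offset at the 50th percentile for fetal alcohol against control diet. Against isocaloric diet they rose to 3 under both scalings. Leaving out 1 array at a time gave 0 to 25, 0 to 12 and 0 to 13 in the 3 comparisons, highest without fetal alcohol array 2. A fit that leaves out a fetal alcohol array takes its spread from the control diet arrays, the closest pair, and has 1 fetal alcohol array fewer. These act on the standard errors in opposite directions. The rule of size gave 124 probe sets with the offset at the 50th percentile, 496 with no filter, 176 with the filter at the 60th percentile, 54 at 2-fold, 148 with the isocaloric array on the control side and 468 to 713 without 1 array, where 1 array faces 2 and overlap is rarer by construction (468 and 471 without control diet array 1 and 2, 613 and 713 without fetal alcohol array 1 and 2). The correlation of the 2 differences was 0.522 with the offset at the 50th percentile, 0.485 with no filter, 0.524 with the filter at the 60th percentile and 0.348 to 0.5998 without 1 array, lowest without fetal alcohol array 2. Except where stated, the cause was not tested.

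The replicate numbers were not taken to pair the samples. With the replicate block 8 probe sets and 7 lists passed for fetal alcohol against control diet, and with the numbers crossed 21 probe sets.

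No ranked gene changed sign, and 22 of the 90 differences of named genes did so, none of which passed the threshold. For fetal alcohol against control diet, ranked genes were chosen without overlap between the groups. Leaving out 1 array could therefore not change their sign. For fetal alcohol against control diet, leaving out 1 array gave ranges of -0.12 to 0.14 for Gap43, -0.15 to 0.49 for Ntrk2, -0.12 to 0.28 for Igf1, -0.091 to 0.57 for Mbp, -0.35 to 0.54 for Grin1, -0.22 to 0.12 for Gria2, -0.37 to 0.29 for Gad1 and -0.12 to 0.15 for Npy. Against isocaloric diet the ranges were -0.072 to 0.18 for Gap43, -0.24 to 0.40 for Ntrk2, -0.20 to 0.044 for Grin1, -0.38 to 0.28 for Gad1 and -0.013 to 0.21 for Npy. Between the diets they were -0.17 to 0.074 for Gap43, -0.063 to 0.24 for Ntrk2, -0.18 to 0.22 for Igf1, -0.53 to 0.0033 for Igf2, -0.37 to 0.30 for Mbp, -0.28 to 0.61 for Grin1, -0.043 to 0.071 for Gad1 and -0.22 to 0.048 for Npy. Quantile normalization turned Npy to -0.016 (fetal alcohol against control diet), Mbp to 0.027 and Gad1 to -0.00856 (between the diets), equal medians turned Mbp to 0.0013, and with both diets as 1 group Gria2 had 0.081 and Fos 0.083. Signal over background limits the dim probe sets: between 19.0% and 20.7% of the values of each array lay under the offset, where log2 differences shrink. For fetal alcohol against control diet, the alternatives gave -2.35 to -0.86 for Gsta1 and -2.42 to -1.19 for Sod3. They gave -2.89 to -1.54 for Igf2 (E00988mRNA_s_at), the last with the offset at the 50th percentile.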

Other observations

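The tests of explanations below were chosen after the results were seen, except those of a second choroid plexus list and of the covariance under quantile normalization; the gene lists were fixed beforehand. Lists that passed no test covered further cell types. For fetal alcohol against control diet, microglia and macrophage genes had a median log2 difference of -0.28 over 12 genes (camera adjusted p = 0.113), with C1qb, a complement component, at -0.69 ± 0.35. Endothelium and pericyte genes had -0.24 over 13 genes (adjusted p = 0.084), and red blood cell genes -0.23 over 5 (adjusted p = 0.121). Astrocyte genes had -0.12 over 21 (adjusted p = 0.413), oligodendrocyte and myelin genes -0.01 over 13 (adjusted p = 0.747) and markers of neighbouring brain regions 0.10 over 15 (adjusted p = 0.331). Heat shock and unfolded protein genes had the highest median, 0.21 over 21 genes (adjusted p = 0.204), with a mean of 0.13. Antioxidant and glutathione genes had -0.05 over 31 (adjusted p = 0.196), although Sod3 and Gsta1 belong to them, and cell cycle genes 0.0024 over 20 (adjusted p = 0.536).

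Of the 8 choroid plexus genes, 6 were lower on both fetal alcohol arrays than on all 3 arrays of the diets. A difference in scaling is argued against, since the list's median stayed at -0.859 or below under quantile normalization and equal medians, and 1 array alone is too, since the median was -0.641 or below without either fetal alcohol array. A smaller share of choroid plexus tissue in the fetal alcohol samples may account for the pattern: a second list of 20 tested choroid plexus genes, none shared with the first, had a median at percentile 0.41 of matched random lists against control diet, but at 17.5 against isocaloric diet, so it stays open. Lower expression per choroid plexus cell cannot be told apart from it, because the second list's median of -0.193 lies between 0 and that of the first list, and how many of its genes the hippocampus itself expresses was not analysed here. The Ttr signal of the fetal alcohol arrays themselves differed by 3.67 on the log2 scale, while the median of the 7 other choroid plexus genes differed by 0.164.

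The fetal alcohol and isocaloric arrays shared part of their differences from control diet. The covariance of 0.0655 lay above all simulations with shared controls alone, and it stayed above 0 with separate control arrays (0.0406 and 0.0323), which argues against shared control arrays as the whole cause. A scaling that depends on intensity is argued against, since the covariance beyond the simulated one was 1.09 times as large under quantile normalization. Hybridisation of the control diet arrays apart from the others may account for it, while labelling of the samples was not tested separately. All 4 spiked control RNAs were brighter on both control diet arrays than on the 3 others, by at least 0.153 on the log2 scale. Chance gives each such an order in 10% of cases, and the 4 are not independent, since they share the scaling of each array. RNA quality of the control diet arrays cannot be told apart from labelling or hybridisation. Their beta-actin 3' to 5' ratios lay above those of the others by at least 0.0656, while the Gapdh ratios overlapped. A shared effect of both treatments on the hippocampus was not tested.

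On the isocaloric array, ribosomal protein genes were higher and synaptic vesicle genes lower than on the control diet arrays. The 3' to 5' ratios do not decide on degraded RNA, because they point in opposite directions. The beta-actin ratio of the isocaloric array was 1.12, the lowest of the 5 arrays. Its Gapdh ratio of 0.931 lay above the 0.878 and 0.895 of the control diet arrays. The highest Gapdh ratio, 0.984, was that of fetal alcohol array 1. Scaling is argued against, since both lists' medians kept their signs and a size of at least 0.27 under quantile normalization and equal medians. With 1 array, a difference in dissection, the brighter control RNA and higher beta-actin ratios of the control diet arrays and an effect of the diet stay open and were not tested for these lists.

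By the rule of size, the real split of the 4 control diet and fetal alcohol arrays gave 286 probe sets and the highest other split 293; the 3 splits are too few for a share under 0.05.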
